A study of Escherichia coli and Staphylococcus aureus with 12 samples.

How the data were processed

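RNA sequencing of bacteria was analysed in 4 groups of 3 libraries. Per the labels, Escherichia coli and Staphylococcus aureus were either left untreated or exposed to AuPt@ZIF-8, a zinc imidazolate framework carrying gold and platinum, together with hydrogen peroxide and near-infrared light. Per the labels' protocols, total RNA was treated with DNase, checked for integrity, depleted of ribosomal RNA and made into strand-specific libraries that were read as pairs. The submitters' processing notes name fastp, a tool that trims and filters reads, without a version. The aligner, the counting tool, the genome build and any use of the strand in counting are not given in the sources used here.

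The authors deposited, per the file headers, 1 table of estimated counts and 1 table of TPM (transcripts per 1000000) for each of the 2 labels. The estimated counts per gene were not normalized, and 49 to 80 cells of each library held fractions, so that they were rounded to whole numbers here. The deposited TPM values sum to 1000000 in each library and were used only in alternatives. The table labelled E. coli held 4533 rows and the table labelled S. aureus 4580 rows. In both, 4433 rows carried E. coli locus tags, and all 4433 matched the name table of assembly ASM584v2 (E. coli K-12 MG1655), which was used for names, lengths and neighbours and for no coordinates. The other rows were 44 and 66 transcripts that the tables number without a gene name, and 56 and 81 small RNAs, also without names. Under the E. coli label, the numbered transcripts took 28.2% to 36.2% of the counts of untreated and 34.0% to 40.5% of treated libraries. Under the S. aureus label they took 13.0% to 20.2% and 19.0% to 32.6%. Nearly all of these counts lay in 2 transcripts. The numbered transcripts stayed in the library sizes and tests, and their removal was an alternative. No row was annotated as ribosomal RNA, so the planned removal of ribosomal RNA rows was not run. Whether numbered transcripts hold ribosomal RNA is not known. Each sample column matched the title of 1 sample, and 0 sample columns were left over.

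Library totals lay between 7178632 and 9870488 counts. Treated and untreated libraries of each label were compared with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM scaling, the filterByExpr filter, two-sided p-values and Benjamini-Hochberg adjustment over the genes tested, at 0.05. Values per library are TMM-scaled counts per 1000000 (CPM), computed here from the deposited counts, and standard errors of log2 fold changes were derived from the F statistic. All fold changes are treated over untreated unless stated otherwise. Gene lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, over lists with at least 3 tested members. The test was repeated with an estimated correlation, and fry asked whether the genes of a list moved one way on balance. Responses were compared between the labels over symbols naming 1 tested row in each table, with a limma voom interaction term, and their correlation across genes was tested with 100000 permutations. The labels do not say that libraries came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

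The gene lists, tests, alternatives and the rule for named genes were fixed before the data were examined. The rule took, per label, the 5 largest rises and 5 largest falls among genes past the threshold with at least 10 CPM on average and with all 3 treated libraries on one side of the untreated ones, which 10% of groupings of 6 libraries give by chance. It added the 3 members with the largest change from each of the 6 lists with the smallest camera p and from the lists on peroxide, superoxide, zinc, heat shock and DNA damage, and the 4 shared genes with the largest difference between the labels. Lists were fixed for each species, 43 for E. coli and 42 for S. aureus. Since the table labelled S. aureus held E. coli genes, the E. coli lists were also applied to it, a choice made after the data were seen. The restriction to genes of at least 10 CPM, the removal of numbered transcripts and the list test on the difference between the labels were chosen at the same stage. That restriction also redid the library sizes and scaling and changed the genes a list was compared with. Calls and medians could therefore move in lists that lost no member. The alternatives fixed at the outset were the size factors of DESeq2, upper-quartile scaling, library size alone, no filter, the Wald test of DESeq2 1.42.0, limma voom, limma-trend on log2 TPM with a pseudocount of 1 or 0.1 for genes of at least 1 TPM, a fold change of at least 2, a replicate block and leaving out each library.

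The tests were tried on simulated counts with 200 changed genes. For the E. coli comparison, run on 3521 genes, edgeR recovered 83 of 100 genes changed 2-fold and 100 of 100 changed 4-fold, with 7.11% of calls false. For the libraries labelled S. aureus, run on 3548 genes, it recovered 85 and 100 of 100, with 7.04% of calls false. The interaction test, run on 3475 genes, recovered 51 of 100 genes whose responses differed 2-fold and 89 of 100 that differed 4-fold, with 4.11% of calls false. A list of 15 genes raised 2-fold was called by camera for both labels, and 0 of 42 other lists were. Simulated genes were drawn independently of one another. That trial therefore cannot show how often lists of correlated genes are called falsely. As many simulated genes rose as fell, and most did not change. In the data 58.2% and 40.4% of tested genes were called under the E. coli and S. aureus labels. The trial therefore does not test the scaling under so wide a change, and its rates need not hold there. Counting intervals cover counting error only, since reads amplified by PCR are not independent molecules. The CspA family holds similar genes, and ynaE and ydfK are near copies of one another, so counts of these genes are uncertain where the counting could have split shared reads. The same holds for short neighbouring or overlapping genes such as cspG and ymcF.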

Results

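Transcript levels were measured by RNA sequencing in 12 bacterial libraries, 3 in each of 4 groups. The groups were untreated and treated E. coli and untreated and treated S. aureus, as labelled. The treatment combined AuPt@ZIF-8, a zinc-containing nanomaterial carrying gold and platinum, with hydrogen peroxide and near-infrared light. Total counts were 7178632 to 8333504 in the untreated and 7849903 to 8768336 in the treated libraries labelled E. coli. Those labelled S. aureus held 7418603 to 9691575 untreated and 7930606 to 9870488 treated. Between 3375 and 3578 rows reached 10 counts in each library.

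The genes of the table labelled S. aureus that could be identified were not S. aureus genes. All 4433 of its reference rows were E. coli genes, the same as in the table labelled E. coli. Genes that S. aureus, a bacterium without an outer membrane, lacks were counted at similar levels under both labels. Over 30 tested genes of lipopolysaccharide synthesis and transport and of outer membrane porins, the median log2 ratio of untreated levels, S. aureus label over E. coli label, was 0.16, with single genes between -1.46 and 0.93. Untreated libraries of the 2 labels correlated across genes with a Spearman rho of 0.964 to 0.985, against 0.976 to 0.995 for libraries of one group. Fewer than 6 counts over 6 libraries were found for 749 genes under both labels, for 14 genes under the E. coli label alone and for 16 under the S. aureus label alone. Of the 749 genes, 401 lay in runs of at least 5 neighbours, against at most 26 in 10000 random orders, and the longest run was 35 genes, against 9. Random orders ignore that neighbouring genes are often transcribed together, so these runs cannot tell absent genes from silent ones. The 2 tables were not copies, since even the closest pair of libraries across labels differed by a chi-square of 41.9 per degree of freedom, where copies would give about 1 and pairs within one group gave 23.6 to 158. That pair was treated replicate 3 of the E. coli label and treated replicate 2 of the S. aureus label, and the latter differed from the other treated replicates of its own label by 64.8 and 158. The second set is therefore called the libraries labelled S. aureus throughout, and nothing here describes S. aureus.

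In the libraries labelled E. coli, the question was which transcripts changed after treatment. Members of the CspA family, small RNA-binding proteins of which several are known for their induction in the cold, were among the deepest falls. The transcript of cspB went from 1713 ± 1616 to 2.33 ± 1.32 CPM (SD, n = 3), a log2 fold change of -9.52 ± 0.71 (SE, edgeR adjusted p = 3.4e-07). Untreated replicate 2 held 3568 CPM of cspB against 960 and 610.3 in the others, and without it the log2 fold change was -8.39. The transcript of cspG went from 5742 ± 1311 to 13.4 ± 1.62 CPM (-8.74 ± 0.27, edgeR adjusted p = 3.65e-11), and cspI from 116 ± 12.6 to 0.733 ± 0.463 CPM (-7.29, and -7.90 without treated replicate 2). The small genes ynfT (-7.51) and ymcF (-7.33) completed the 5 largest falls, and ymcF is the neighbour of cspG. Of the cold shock list, 7 of 12 tested members were lower and 2 higher, the same adjusted over the list alone (camera adjusted p = 0.00977, and 0.372 with an estimated correlation). Chosen after their values were seen, cspA fell from 28646 ± 3015 to 915 ± 322 CPM, lpxP, which adds a cold-specific acyl chain to lipid A, by a log2 fold change of -3.37, and the helicase gene deaD by -2.12, whereas cspC (1.47) and cspD (1.28) rose.

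Most heat shock genes rose in the same libraries. Of 20 tested chaperone and protease genes, 17 were higher and 2 lower, the same adjusted over the list alone (median log2 fold change 0.87, camera adjusted p = 0.000176, and 0.372 with an estimated correlation). The small heat shock protein gene ibpB rose from 98.6 ± 1.58 to 624 ± 159 CPM (SD, n = 3, edgeR adjusted p = 1.73e-07). The disaggregase gene clpB rose from 1161 ± 228 to 4544 ± 151 CPM, and ibpA showed a log2 fold change of 1.72 ± 0.26. The acid-stress chaperones hdeB (3.07 ± 0.26) and hdeA (2.95 ± 0.29) were the 2 largest rises of all, with hdeA going from 30.5 ± 6.62 to 236 ± 100.01 CPM. They belong to the acid resistance list, in which 5 of 14 members were higher and 4 lower, also adjusted over the list alone, with no call for the list (camera adjusted p = 0.671).

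Several genes of zinc export rose, and some of zinc uptake fell. Of 7 zinc export genes, 5 were higher and none of the 7 was lower (camera adjusted p = 0.00977, and 0.372 with an estimated correlation). The zinc-exporting ATPase gene zntA rose from 97.4 ± 11.3 to 248 ± 47.5 CPM (edgeR adjusted p = 2.09e-05), and its regulator zntR (1.54) and the sensor kinase gene zraS (1.33) rose as well. For zinc uptake, 4 of 6 tested members were lower and 1 higher, and the list was not called (camera adjusted p = 0.116). The transporter genes znuC (-1.70 ± 0.16) and znuA (-1.53 ± 0.15) fell, and pliG, a lysozyme inhibitor, rose (1.45 ± 0.23). The counts of both zinc lists were the same adjusted over the list alone.

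Among the peroxide defence genes of the OxyR list, 8 of 13 were higher and 0 lower, also adjusted over the list alone (camera adjusted p = 0.0179, and 0.372 with an estimated correlation). The DNA-binding ferritin gene dps rose from 162 ± 25.3 to 603 ± 112 CPM (edgeR adjusted p = 2.85e-06), the cytochrome c peroxidase gene ccp by 1.70 ± 0.19 and the alkyl hydroperoxide reductase gene ahpC by 1.16 ± 0.17 in log2 fold change. With genes under 10 CPM left out and scaling redone, the adjusted camera p of this list was 0.0987 over 12 of its 13 members. Its median was 0.33 in place of 0.48. The SoxRS superoxide list had 11 higher and 3 lower of 22, or 11 and 4 adjusted over the list alone, and was not called (camera adjusted p = 0.131). Its members fumC (1.27) and fpr (1.14) rose and marR (-1.29) fell. Other oxidant-removing and protein-repair enzymes had 11 of 18 members higher and 1 lower (camera adjusted p = 0.0247, and 0.372 with an estimated correlation), the same adjusted over the list alone.

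Higher genes outnumbered lower ones in the lists on energy metabolism and on arginine and pyrimidine synthesis. In the tricarboxylic acid cycle 18 of 19 members rose and 0 fell (median 1.15, camera adjusted p = 1.15e-05, and 0.372 with an estimated correlation), led by the glyoxylate shunt genes aceB (1.95 ± 0.34) and aceA (1.89 ± 0.19) and by sucA (1.65 ± 0.17). All 9 ATP synthase genes rose (camera adjusted p = 0.00197, and 0.372 with an estimated correlation), with atpG at 1.33, atpE at 1.27 and atpA at 1.16. Of the aerobic respiratory chain, 15 of 21 tested members rose and 1 fell (camera adjusted p = 0.00109, and 0.521 with an estimated correlation), among them the NADH dehydrogenase genes nuoG (1.33), nuoE (1.30) and nuoF (1.22). Arginine synthesis had 9 of 10 tested members higher, 10 adjusted over the list alone (camera adjusted p = 0.0011, and 0.526 with an estimated correlation). It includes carA (2.16 ± 0.19) and carB (1.81 ± 0.18), which make the carbamoyl phosphate shared with pyrimidines, and argI (1.43 ± 0.34). Pyrimidine synthesis had 7 of 10 higher and 1 lower (camera adjusted p = 0.00592, and 0.552 with an estimated correlation), and its aspartate transcarbamoylase gene pyrB went from 17.2 ± 1.68 to 125 ± 22 CPM (edgeR adjusted p = 3.25e-08). The citrate carrier gene citT (2.80 ± 0.29) and the trehalose 6-phosphate hydrolase gene treC (2.69 ± 0.21) were the remaining largest rises. The counts of the lists other than arginine synthesis were the same adjusted over the list alone.

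Further lists called in the libraries labelled E. coli were higher for purine synthesis (10 of 14 higher, 0 lower, camera adjusted p = 0.00466), glycolysis (10 of 13 higher, 1 lower, 0.00592), anaerobic respiration and fermentation (16 of 38 higher, 3 lower, 0.00977), outer membrane porins (8 of 11 higher, 3 lower, 0.0392) and methionine synthesis (8 of 12 higher, 1 lower, 0.0475). With an estimated correlation their adjusted p lay between 0.372 and 0.639, and the counts were the same adjusted over the list alone. With genes under 10 CPM left out, the camera adjusted p was 0.0829 for anaerobic respiration (median 0.27 in place of 0.39) and 0.138 for methionine synthesis (0.46 in place of 0.58), whose call also ended by library size alone (0.0568). Anaerobic respiration kept 37 of 38 tested members there. Methionine synthesis kept all 12, so low-level members cannot account for its change.

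Lower genes outnumbered higher ones in the lists on DNA damage, motility, iron uptake and phosphate. Of the SOS list, 14 of 23 tested members fell and 1 rose (median -0.62, camera adjusted p = 0.00661, and 0.372 with an estimated correlation), including recX (-1.22), dinF (-1.20) and symE (-1.20). Flagella and chemotaxis had 23 of 43 tested members lower and 1 higher (median -0.83, camera adjusted p = 0.000117, and 0.521 with an estimated correlation). The serine receptor gene tsr showed -0.95 ± 0.18, the filament cap gene fliD -0.68 ± 0.22 and the aerotaxis gene aer -0.40 ± 0.16. The call of fliD ended without untreated replicate 3 (edgeR adjusted p = 0.0757) and without treated replicate 2 (0.0888), at log2 fold changes of -0.53 and -0.51. That of aer, at an edgeR adjusted p of 0.0415, ended under 8 alternatives, at adjusted p of 0.0552 to 0.155 and log2 fold changes of -0.31 to -0.42. Siderophore and iron uptake had 18 of 40 members lower and 1 higher (camera adjusted p = 0.00977), and phosphate starvation 12 of 17 lower and 3 higher (0.0331), with adjusted p of 0.672 and 0.372 with an estimated correlation. Counts over these 4 lists were the same adjusted over the list alone. Low-level genes were more often lower than higher in these libraries, with a median log2 fold change of -0.77 over the 776 tested reference genes under 10 CPM and 0.12 over the 2711 at or above it. With genes under 10 CPM left out, the adjusted camera p was 0.0416 for flagella, with a median of -0.46 over 12 members, and 0.222 for phosphate starvation, with a median of -0.64. The phosphate call also ended by upper quartile and by library size alone (0.0568 for both), although the median was deeper there, at -0.95 and -1.03 against -0.73. The same restriction to 10 CPM added calls for ribosomal proteins (median -0.36, camera adjusted p = 0.011) and lipopolysaccharide synthesis and transport (median -0.38, 0.0486), both lower. These lists kept 52 of 53 and 19 of 19 tested members, so loss of members cannot account for the lipopolysaccharide call.

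In total, 1018 of 3521 tested genes were higher and 1032 lower after treatment in the libraries labelled E. coli, and 345 and 559 of them changed at least 2-fold. The split depended on the scaling, with 615 higher and 1487 lower by library size alone and 750 and 1344 by upper quartile. The median log2 fold change of all genes was -0.32 and -0.24 there, in place of -0.03. By limma-trend on log2(TPM + 1) it was 464 and 1142, with a median of -0.25. That alternative also changed the test and the filter, so its split cannot be put down to scaling alone. Of 42 lists tested, 14 were called higher and 5 lower. No list was called with an estimated correlation in camera, where 2 had an unadjusted p under 0.05, and fry called 25.

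**Figure D1:**
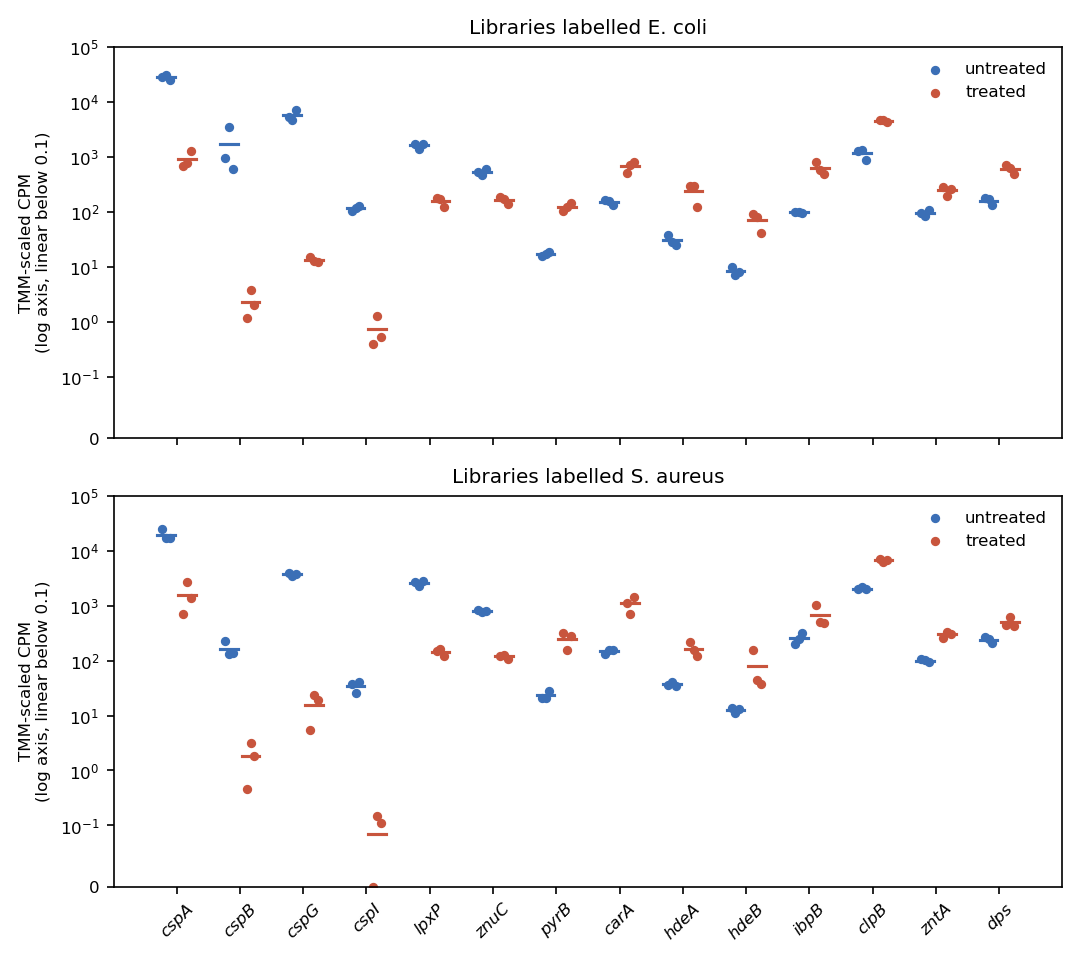
TMM-scaled CPM of 14 genes in each of the 12 libraries, on a log axis that is linear below 0.1, with points for libraries and bars for the mean of 3. In both sets cspA, cspB, cspG, cspI, lpxP and znuC were lower in all treated libraries, and the other 8 genes were higher.

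In the libraries labelled S. aureus, the same question gave a similar set of genes, and all genes named here are E. coli genes. Genes for carbamoyl phosphate and pyrimidines made up 3 of the 5 largest rises, with pyrB going from 23.3 ± 3.95 to 250.1 ± 82.1 CPM (SD, n = 3), a log2 fold change of 3.42 ± 0.27 (SE, edgeR adjusted p = 4.92e-05). Its neighbour pyrI showed 2.86 ± 0.23 and carA 2.88 ± 0.25, with citT (3.09 ± 0.29) and hdeB (2.66 ± 0.51) as the other largest rises. Treated replicate 1 held 156 CPM of hdeB against 45.1 and 37.6 in the others, and without it the log2 fold change was 1.65. The deepest falls again included cspI and cspG. The counts of cspI went from 966 to 2 over the 3 libraries of each arm, a ratio of 432 after scaling for library size, with a 95% exact conditional interval of 119 to 3573. The transcript of cspG went from 3718 ± 269.7 to 15.8 ± 9.28 CPM (edgeR adjusted p = 1.51e-05), and ynaE (-7.75), ymcF (-7.63) and ynfT (-7.43) followed in log2 fold change. Reads of ynaE and its near copy ydfK (-5.16) could have been shared.

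By the E. coli lists, applied to these libraries after the data were seen, 12 of 42 lists were higher and 3 lower, and 0 were called with an estimated correlation. Each list is given with its camera adjusted p, followed by that with an estimated correlation. Purine synthesis had 12 of 14 members higher, 13 adjusted over the list alone (1.59e-05, 0.53), pyrimidine synthesis 9 of 10 (7.92e-05, 0.53) and arginine synthesis 10 of 10 (5.68e-05, 0.53). The tricarboxylic acid cycle had 16 of 19 higher and 1 lower (3.11e-05, 0.53), the aerobic respiratory chain 15 of 21 higher (0.000411, 0.53) and ATP synthase 8 of 9 (0.000856, 0.53). Heat shock genes had 12 of 20 higher and 1 lower (0.00111, 0.506), zinc export 5 of 7 higher (0.0343, 0.53), and methionine synthesis (0.00393, 0.54), porins (0.0192, 0.53) and glycolysis (0.0263, 0.812) were also higher. Flagella and chemotaxis had 13 of 45 members higher and 1 lower (0.0163, 0.812). Lower were the SOS list, with 17 of 23 members lower and 1 higher (1.59e-05, 0.53), the cold shock list, with 8 of 12 lower and 2 higher (0.00133, 0.53), and zinc uptake, with 5 of 7 lower and 0 higher (0.00252, 0.506). Adjusted over the list alone, 19 SOS genes were lower, 13 heat shock genes and 1 zinc uptake gene higher and 1 respiratory chain gene lower, and the other counts given were the same. With genes under 10 CPM left out, glycolysis and zinc export were not called (camera adjusted p = 0.0522 for both), with medians of 0.52 and 0.95 in place of 0.58 and 1.02. Both lists kept all their members, 13 and 7, so low-level members cannot account for this. The OxyR list had 7 of 13 members higher and 1 lower and was not called (0.375, 0.812), and neither was the SoxRS list, with 6 of 22 higher and 5 lower (0.972, 0.992).

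The lists fixed for S. aureus met these libraries only through gene symbols or synonyms that E. coli shares, and 30 of 42 had at least 3 tested members. Of these, 6 were higher and 2 lower, none with an estimated correlation. A match by name need not be the same gene or function. Examples are prs in the heat shock list, mreB in the zinc uptake list and yjbH in the thiol and methionine repair list. The heat shock list, with prs counted through a synonym alone, had 10 of 13 tested members higher, 11 adjusted over the list alone (camera adjusted p = 8.5e-05, and 0.278 with an estimated correlation). Its members groL, clpB and hslO showed log2 fold changes of 1.73, 1.70 and 1.39. The other lists called higher were purine synthesis, with purH (1.67), purD (1.56) and purL (1.54), pyrimidine synthesis, with carB (1.88), and ATP synthase, with atpE (1.33), atpG (1.20) and atpA (1.19). Lysine and threonine synthesis, with thrA (1.52), thrB (1.39) and thrC (1.35), and cysteine and methionine synthesis were called higher too. The camera adjusted p of these 5 lists ran from 0.00035 to 0.0271, and was 0.563 for each with an estimated correlation. The SOS list had 9 of 15 members lower (0.00736), with recX (-1.56), dinB (-1.36) and lexA (-1.18), and iron-sulfur cluster assembly 4 of 6 lower (0.0273). Both lower lists had an adjusted p of 0.563 with an estimated correlation, and their counts were the same adjusted over the list alone. The E. coli list of iron-sulfur cluster assembly, with 18 tested members in these libraries, was not called (median 0.19, camera adjusted p = 0.999). It had 3 members higher and 5 lower, or 6 and 5 adjusted over the list alone. With genes under 10 CPM left out, cysteine and methionine synthesis (camera adjusted p = 0.0506) and the iron-sulfur list fixed for S. aureus (0.0819) were not called. Their medians were 0.57 and -0.84 in place of 0.63 and -0.92. The first kept all 16 tested members and the second 5 of 6.

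The treatment-directed lists fixed for S. aureus gave single genes in these libraries. The ferritin gene dps rose from 240.1 ± 29.6 to 494 ± 105 CPM (edgeR adjusted p = 0.00161), bcp by 0.79 ± 0.21 and the thioredoxin reductase gene trxB by 0.74 ± 0.13 in log2 fold change, in a peroxide list with 5 of 8 tested members higher, also adjusted over the list alone (camera adjusted p = 0.128). The repair gene msrA (1.22 ± 0.22) and the superoxide dismutase gene sodA (0.71 ± 0.17) rose in a list with 3 of 6 tested members higher, also adjusted over the list alone (camera adjusted p = 0.415). On the zinc side, zntA rose from 99.7 ± 6.5 to 299 ± 37.4 CPM (edgeR adjusted p = 8.49e-05) and zntR by 1.25 ± 0.19, from a list with too few tested members for a list test. The uptake gene znuB fell (-1.82 ± 0.20), as did zur (-0.73 ± 0.19), the gene of the zinc uptake repressor, in a list with 2 of 3 tested members lower, also adjusted over the list alone, that was not called (camera adjusted p = 0.145). The remaining tested member was mreB, matched by name alone. The calls of bcp and sodA ended by library size alone (edgeR adjusted p = 0.0898 and 0.099) and without untreated replicate 2 (0.0693 and 0.0511), at log2 fold changes of 0.52 and 0.44 and of 0.65 for both. That of zur ended without untreated replicate 1 or 2 (edgeR adjusted p = 0.0527 and 0.0631), at -0.68 and -0.60. On log2 TPM by limma, the calls of dps, bcp, trxB, msrA, sodA, zntR, thrC, atpE, atpG and atpA ended with either pseudocount and that of hslO with a pseudocount of 0.1, at adjusted p of 0.0528 to 0.603.

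In total, 768 of 3548 tested genes were higher and 665 lower in the libraries labelled S. aureus, and 279 and 305 of them changed at least 2-fold. Scaling again moved the split, to 374 higher and 991 lower by library size alone and to 627 and 760 by upper quartile. The median log2 fold change of all genes was -0.25 and -0.05 there, in place of 0.04. With the numbered transcripts removed, 665 genes were higher and 725 lower, with a median of -0.02. By limma-trend on log2(TPM + 1), which also changed the test and the filter, 86 were higher and 572 lower, with a median of -0.29. No list of either set was called with an estimated correlation in camera, where 2 of the S. aureus lists and 3 of the E. coli lists had an unadjusted p under 0.05, and fry called 16 of each.

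**Figure D2:**
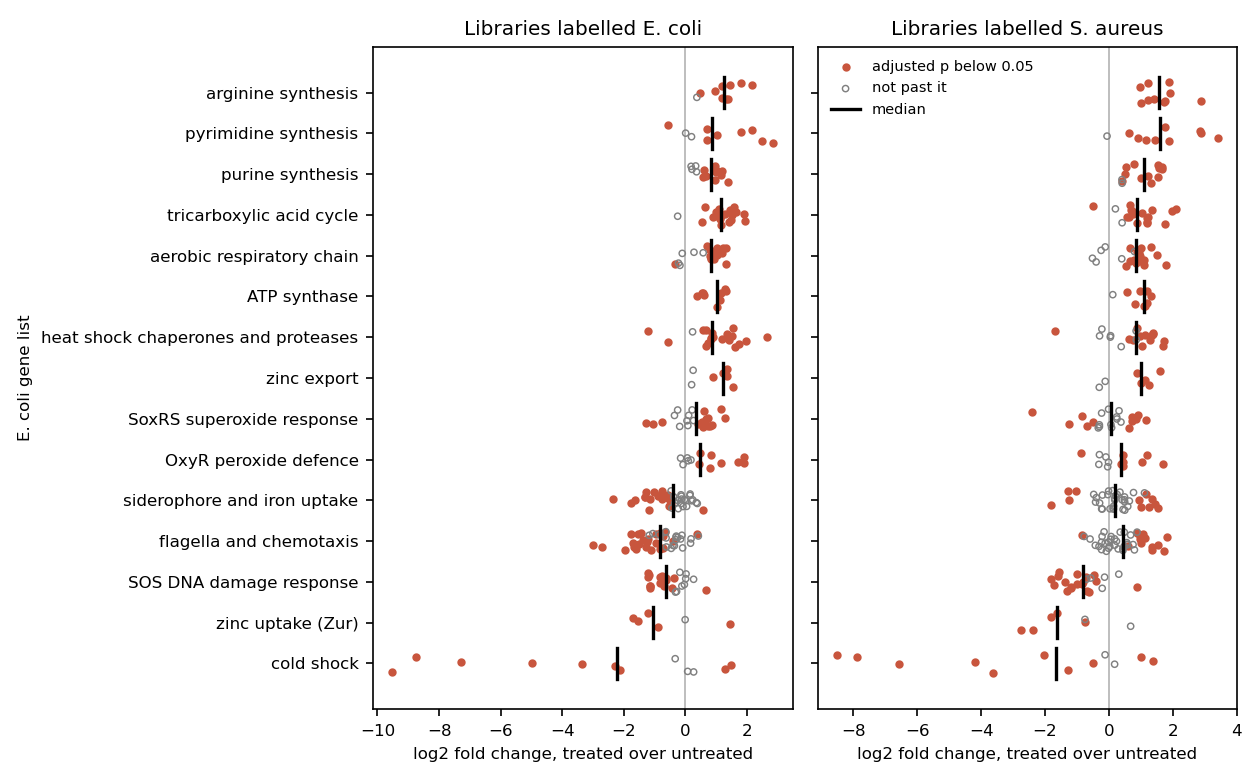
Log2 fold changes, treated over untreated, of the tested members of 15 E. coli gene lists in both sets of libraries. Each point is a gene, filled where its edgeR adjusted p was below 0.05, and the black bar is the median of the list. The median of the flagella and chemotaxis list lay at -0.83 in the libraries labelled E. coli and at 0.44 in those labelled S. aureus, and that of the cold shock list at -2.21 and -1.65.

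The 2 sets were compared over 3459 shared genes, to ask whether their responses differed. The sets share no library. Responses correlated across genes, which are not independent replicates, with a Spearman rho of 0.735 and a Pearson r of 0.734 (two-sided permutation p = 1e-05 for each, the smallest that 100000 permutations can give). Of genes called in both, 1132 of 1143 had the same sign. Among shared genes, 642 were higher in both sets, where independent lists would share 222, and 490 were lower in both, where independent lists would share 191. Of the E. coli lists, 14 were called in both sets, 13 of them in the same direction, and with an estimated correlation camera called 0 in either set.

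Flagellar genes were among those that differed, with 9 of the 42 shared members of that list called, all with a more positive response in the libraries labelled S. aureus. The interaction test called 29 of 3459 genes, 14 with a more positive response in the libraries labelled S. aureus and 15 with a more negative one. The cap gene fliD differed by a log2 value of 2.18 ± 0.36 (SE, limma adjusted p = 0.0084), at -0.68 under the E. coli label and 1.53 under the S. aureus label. The flagellin gene fliC differed by 1.91 ± 0.30 (limma adjusted p = 0.0084). It was not called under the E. coli label (-0.16, edgeR adjusted p = 0.547) and rose by 1.80 under the S. aureus label. In the opposite direction, ibpA differed by -2.04 ± 0.38 (limma adjusted p = 0.0165) and the galactose transport gene mglA by -1.82 ± 0.33 (limma adjusted p = 0.0155). Both rose under the E. coli label (1.72 and 2.38). Neither was called under the S. aureus label (-0.29 and 0.51, edgeR adjusted p = 0.256 and 0.144). Untreated levels, E. coli label first, were 19.4 and 61.1 CPM for fliC and 17.8 and 58.6 for fliD. They were 575 and 1512 for ibpA and 15.8 and 13.5 for mglA. The number of differing genes depended on single libraries. It was 304 and 91 without replicates 1 and 2 of the treated libraries labelled S. aureus and 105 without replicate 3 of the treated libraries labelled E. coli. It fell to 16 without untreated replicate 2, 15 without treated replicate 1 and 12 without treated replicate 2 of the E. coli label. For the S. aureus label it fell to 15, 15 and 18 without untreated replicates 1, 2 and 3 and to 15 without treated replicate 3. The call of ibpA ended without treated replicate 1 or 2 of the E. coli label and without untreated replicate 2 or treated replicate 3 of the S. aureus label (limma adjusted p = 0.0542 to 0.0586), with differences of -1.85 to -2.06 that were close to the full value. That of mglA ended without treated replicate 2 of the E. coli label and untreated replicate 1 or 2 of the S. aureus label (0.0558 to 0.0655), at -1.64 to -1.75.

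**Figure D3:**
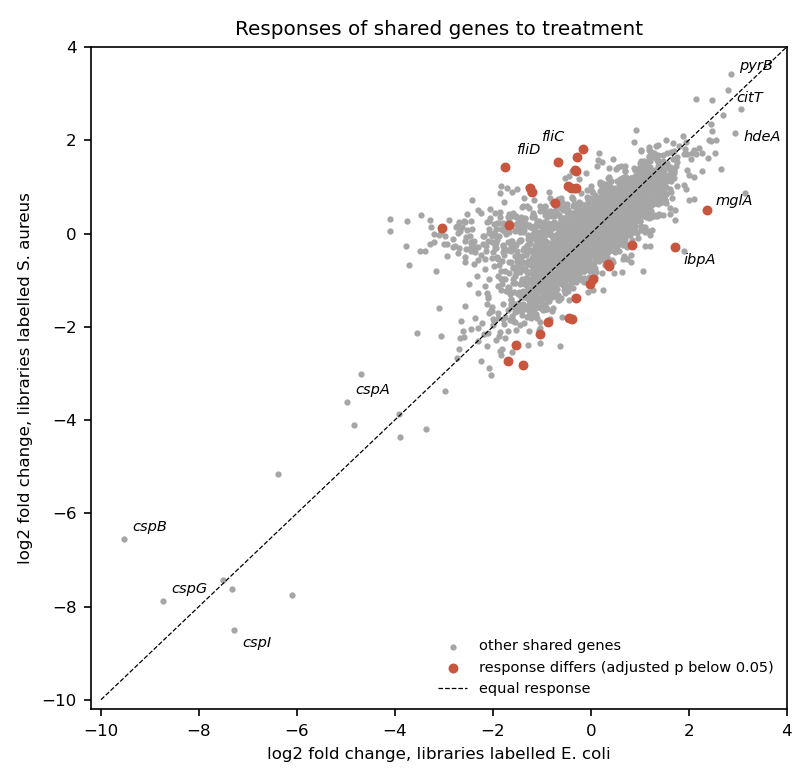
Log2 fold changes of 3459 shared genes in the libraries labelled S. aureus against those labelled E. coli, with 29 genes whose responses differed (limma voom interaction, adjusted p below 0.05) as larger points and a dashed line of equal response. The Spearman rho over all points was 0.735, and cspB, cspG and cspI lay far below 0 in both sets.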

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

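Results are given here where the response to treatment differed between the 2 sets of libraries by a test of the difference itself. The list test on the difference was chosen after the data were seen, and the tests of the flagellar pattern were chosen before their results were seen. Among single genes, fliD (2.18) and fliC (1.91) responded more positively in the libraries labelled S. aureus, and ibpA (-2.04) and mglA (-1.82) more negatively, in log2 units. Splits of the 12 libraries within the sets cannot decide on chance for the number of such genes. At least 29 were called in 7 of 100 splits, the real one included, and the highest other called 2191. All 6 of the others kept the real division of one set, so their difference holds a treatment response by construction. The split with 2191 exchanged treated and untreated libraries in one set only. The 85 drawn splits that kept neither real division called at most 0 genes by limma voom. In those, the response to treatment lies within the compared groups and widens their spread, so they do not exclude chance either.

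By camera with the preset correlation, 11 of 42 E. coli lists differed in response, and with an estimated correlation none of the 11 did, at adjusted p of 0.217 to 0.866. More positive under the S. aureus label, as median differences in log2 units, were flagella and chemotaxis (1.38, adjusted p = 1.28e-19), siderophore and iron uptake (0.76, adjusted p = 1.97e-07), pyrimidine synthesis (0.61, adjusted p = 0.00379) and ribosomal proteins (0.28, adjusted p = 0.00661). More negative were zinc uptake (-0.79, adjusted p = 0.000111), OxyR peroxide defence (-0.41, adjusted p = 0.0177), phage shock (-0.65, adjusted p = 0.0201), tricarboxylic acid cycle (-0.30, adjusted p = 0.023), SOS DNA damage response (-0.22, adjusted p = 0.0241), toxin-antitoxin (-1.09, adjusted p = 0.0241) and SoxRS superoxide response (-0.23, adjusted p = 0.0249).

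The medians of the flagella and chemotaxis list had opposite signs, at -0.83 and 0.44 over 42 shared members, and the difference was positive for 40 of the 42. Single genes past the threshold were fewer, with 23 of 43 tested members lower under the E. coli label and 13 of 45 higher under the S. aureus label, where fry did not call the list (adjusted p = 0.0863). Scaling would have to bring the medians within 0.3 of one another, but the smallest difference over 5 scalings was 1.19. A single library is also argued against, since the difference was at least 0.969 without any 1 of the 12. Members near the count floor were left out in a further test, and the 12 with at least 10 CPM in both sets still differed by 1.31. Low-level genes were more often lower under the E. coli label, and once the median of genes of the same level was taken off, the list medians were -0.37 and 0.47, a difference of 0.847. A difference between the cultures or handling of the 2 sets may remain as a hypothesis, and it was not tested.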

How the results depend on the processing

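The restriction to genes of at least 10 CPM, the removal of numbered transcripts and the E. coli lists in the libraries labelled S. aureus were chosen after the data were seen. The planned removal of ribosomal RNA rows was not run because no row was annotated as such. No named gene changed sign under any alternative, and no called list median did under the other scalings, the only alternatives for which list medians were taken. Among single genes under alternatives, 44 values lost the call and 1342 kept their direction and their side of the threshold, and among list medians under other scalings 3 lost a call, 5 gained one and 334 kept both. Genes higher after treatment numbered 615 by library size alone, 464 and 459 on log2 TPM with a pseudocount of 1 and 0.1, and 345 at 2-fold under the E. coli label, and 374, 86, 82 and 279 under the S. aureus label. Lower genes at 2-fold numbered 559 and 305. Library size alone leaves out the TMM factors and changes nothing else. Under the E. coli label these factors were 0.860 to 0.945 in treated and 1.05 to 1.14 in untreated libraries. Under the S. aureus label they were 0.849 to 0.942 and 1.02 to 1.23. A fold threshold takes fewer genes by construction. For the TPM alternatives the cause was not tested. Without single libraries, 878 to 1031 genes were higher and 835 to 977 lower under the E. coli label, and 530 to 728 and 503 to 784 under the S. aureus label. Genes of at least 10 CPM alone gave 818 higher and 818 lower, and 692 and 680. Removal of the numbered transcripts gave 1033 higher and 1004 lower under the E. coli label. Under the S. aureus label it gave 665 and 725, in place of 768 and 665. With an estimated correlation camera called 0 E. coli lists, 0 S. aureus lists and 0 E. coli lists in the libraries labelled S. aureus, and fry, which asks another question, called 16 S. aureus lists. Genes whose response differed numbered 12 to 304 without single libraries, and the Spearman rho lay between 0.637 and 0.827 without single libraries and at 0.893 over genes called in both sets. For the treated against untreated comparisons, 3 against 3 libraries give 10 splits, too few for a share under 0.05. In 1 of 10 splits as many genes were called for each label (2050 and 1433, highest other 0 for both). As many lists were called in 1 of 10 splits for E. coli (19, highest other 13) and in 2 of 10 for S. aureus lists (8, highest other 11).

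The libraries share replicate numbers, but nothing in the labels says that the numbers pair them. Deviations of same-numbered libraries correlated at -0.14, 0.03 and -0.04 under the E. coli label and at 0.08, 0.02 and 0.13 under the S. aureus label, and not every library correlated best with its own number. Over so few libraries, these values cannot exclude a shared culture or day. With the replicate block, 1018 genes were higher and 1018 lower under the E. coli label and 666 and 598 under the S. aureus label. The block gave 17 E. coli lists, 8 S. aureus lists, 15 E. coli lists in the libraries labelled S. aureus and 38 genes whose response differed. Depth limits the genes under about 10 CPM most, since 1 CPM is 7 to 10 counts per library.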

Other observations

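Several groups of genes of shared function held members that rose after treatment. The groups were chosen after their values were seen, and none was tested as a group. All 7 tdc genes, which take up and degrade threonine and serine, were higher in both sets, with median log2 fold changes of 2.42 under the E. coli label and 1.72 under the S. aureus label. For glycerol 3-phosphate uptake and use, 5 of 5 glp genes were higher under the E. coli label (median 2.01) and 4 of 5 under the S. aureus label (0.81). Both tre genes of trehalose use rose under each label (2.18 and 2.07). Of 5 art genes of arginine uptake, 4 and 5 were higher, with log2 fold changes of 0.16 to 1.69 under the E. coli label and 1.17 to 2.23 under the S. aureus label. For galactose uptake, 3 of 3 mgl genes rose under the E. coli label (2.12) and 1 of 3 under the S. aureus label (0.73). Of 7 cit genes of citrate fermentation, 5 and 4 were higher and 1 lower under each label.

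The balance of higher and lower calls among low-level genes was not tested between the labels. Over tested reference genes under 10 CPM, 376 of 776 were lower and 42 higher under the E. coli label (median -0.77), against 58 and 23 of 737 under the S. aureus label (median -0.04). Below 2 CPM the medians were -1.18 and -0.22. Among 419 genes under 5 CPM with the E. coli label, the loss in CPM correlated with gene length across genes at a Spearman rho of 0.548 (two-sided permutation p = 1e-05, the smallest that 100000 permutations can give). Under the S. aureus label the value over 423 genes was -0.0099 (permutation p = 0.84). Genes are not independent replicates, and these values were looked at after the pattern was seen. CPM are not adjusted for gene length, so longer genes can lose more CPM at an equal fold change. The correlation therefore cannot show a larger fold loss in longer genes, and the contrast between the labels may follow from their medians.

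The tests of the next 2 patterns were all chosen after the results were seen. The reference rows of the table labelled S. aureus held E. coli transcripts. Assignment of S. aureus reads to conserved genes is argued against by lipopolysaccharide and porin genes, whose median log2 ratio between the labels was 0.16. A second deposit of the E. coli libraries is argued against by a lowest chi-square of 41.9 per degree of freedom over 36 pairs across labels. E. coli RNA in these libraries, or a wrong organism label, may be the source. Of the reference genes tested under the E. coli label, 99.2% were also tested here. That test was chosen after the similarity of the 2 tables was seen, so its value adds no support. Where E. coli RNA entered stays open, as does any share of S. aureus RNA, since the numbered transcripts and unnamed small RNAs were not identified.

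The CspA family genes cspA, cspB, cspG and cspI were far lower in the treated libraries of both sets, whereas cspC and cspD were higher in both. Reads moved between family members by the counting would keep their sum, but the log2 ratio of the sum, treated over untreated, was at most -1.77 in either set. This covers the family as a whole. Under the E. coli label the untreated sum was 44609.5 CPM, of which cspG held 5742, cspB 1713 and cspI 116. The sum therefore cannot test cspG, cspB or cspI alone. Scaling is argued against as well, since cspA, cspB, cspG and cspI stayed at or below -3.62 under each of 5 scalings. Whether treated cells were warmer than untreated cells when they were collected stays open. The median of deaD, rbfA, pnp, nusA and lpxP lay at least 2.13 log2 units below that of the heat shock list in both sets, but the directions of deaD, lpxP and the heat shock list were already known, so the value supports nothing. Warming by light, chilling of untreated cells and a response to the material itself cannot be told apart, since the 4 groups hold no library exposed to light or material alone.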
